A study of Mus musculus with 2 samples.

How the data were processed

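Small RNA, with a size range of under 30 per the labels, was sequenced from hindbrain of mouse embryos at embryonic day 12.5, in 2 libraries labelled as biological replicates 1 and 2 from pools of 120 and 88 embryos. The labels put both libraries in the same group and describe them as separate pools of tissue. Both carry the same donor label although each pool holds many embryos, so their separation rests on the replicate numbers and pool sizes in the labels.

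The deposited tables hold whole-number read counts per miRNA gene for each library, made by the authors from alignments to the mm10 assembly with the GENCODE M4 annotation, per the text deposited with the tables. The aligner, adapter trimming, mismatch and length settings and all versions are not given in the sources used here. Each table has a column of counts for both strands together and a column for each strand, without a header. Their layout is that of a gene count table with the gene's own strand in the column before the opposite strand. That reading is inferred from the layout and from the totals, since the column taken as the gene's strand holds nearly all counts in both libraries. The opposite-strand column was left out of the main values, because a miRNA hairpin is read from its own strand. Column totals showed that the values were not normalized.

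Rows that name no gene were left out of all totals. In replicate 1 they gave 15.7% of 5947846 reads as unmapped, 32.7% as matching several positions and 3.98% as outside miRNA genes. In replicate 2 they gave 16.2%, 33.4% and 3.72% of 8656439 reads. No read was tallied as ambiguous. Reads that match several positions are assigned to no gene, which lowers the counts of miRNAs with identical copies. Gene counts also merge the arms of a hairpin, so a mature miRNA from an arm was not measured by itself. Without molecular identifiers, amplified copies of a molecule count as separate reads, and ligation preferences of small RNA libraries act on each miRNA, so ranks between miRNAs carry that uncertainty while the same miRNA in both libraries is comparable.

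The depth was 2764276 assigned counts in replicate 1 and 3946444 in replicate 2. A gene with 0 counts is bounded by 3 counts, which is 1.09 and 0.760 CPM. Shares of lists in a library have exact Clopper-Pearson 95% intervals.

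Gene IDs were matched without version numbers to GENCODE M21 on GRCm38, the same assembly as mm10. This gave symbols, coordinates and hairpin sequences for 1894 of 1973 genes. The other 79 had at most 3 counts in a library. A gene was marked as sharing sequence when its hairpin has an identical run of 20 bases, in the same orientation, in another M21 miRNA hairpin. This holds for 923 genes, 87 of them detected, with 8.00% of the counts. Host genes, looked up for the named genes only, are genes on the same strand that contain the hairpin.

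From the counts, CPM was computed as counts per 1000000 (CPM) of the counts assigned to miRNA genes on their own strand. A gene was called detected with at least 10 counts in both libraries. The agreement of the libraries was described by correlations of log2(CPM + 1) across genes with a mean of at least 10 counts. The spread came from the common dispersion of edgeR 4.0.16 in R 4.3.3 with TMM scaling and an intercept as the only term. Each gene was tested between the libraries with a two-sided exact binomial test on its counts, with the expected share from the assigned totals and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05 and at least 2-fold, with 0.5 added to each count in the ratio. Tables, exact tests and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Random lists and bootstrap draws in the closing section used a fixed seed.

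The groups, tests, alternatives, the 23 miRNA lists and the rule for named genes were fixed before the data were examined. The named genes are the 25 with the highest mean CPM, up to 3 detected members of each list with the highest mean CPM, and up to 10 called genes with a mean of at least 100 counts and the largest ratio. Genes named outside this rule are stated as chosen after their values were seen. The lists cover the let-7, miR-9, miR-124, other neuronal, miR-125 and miR-99/100, miR-17-92, Hox, Dlk1-Dio3, miR-181/miR-30/miR-26/miR-29, pluripotency, choroid plexus, oligodendrocyte, erythroid, leukocyte, endothelium, smooth muscle, mesenchyme, epithelium, sensory organ, multiciliated, muscle, liver and gut, and endocrine miRNAs.

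The alternatives were other count minimums, both strands together, leaving out genes that share sequence, leaving out the most abundant gene, leaving out each library, other pseudocounts, TMM or DESeq2 1.42.0 size factors, DESeq2 dispersions and no minimum fold. The scripts were tested on simulated data. With counts drawn at the real means and depths, the binomial test between the libraries called 85 of 97 genes changed by 2.5-fold, 98 of 100 changed by 4-fold and 1 of 196 unchanged genes, among 393 genes tested. The simulated counts varied by counting noise only. The dispersion fit gave 19.8% for a simulated coefficient of variation of 20%, over 401 genes. No comparison between tissues or ages was made, since other samples are not used here.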

Results

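MicroRNA sequencing was carried out on hindbrain dissected from mouse embryos of the B6NCrl strain at embryonic day 12.5, a stage at which the hindbrain neuroepithelium holds both dividing progenitors and newly formed neurons. The series has 1 group of 2 libraries, labelled as biological replicates 1 and 2 and made from pools of 120 and 88 embryos of both sexes. MicroRNAs (miRNAs) are small RNAs cut from hairpin precursors that repress target messenger RNAs. With 1 group there is no contrast between conditions, and the values below describe the miRNA profile of the tissue and how closely its replicates matched. Replicate 1 had 2764276 counts assigned to miRNA genes on the strand of the gene, as read from the layout of the tables, and replicate 2 had 3946444. Values are counts per 1000000 assigned counts (CPM) or percent of assigned counts, given as mean ± SD (n = 2). A count of 0 allows up to 1.09 CPM in replicate 1 and 0.760 CPM in replicate 2, and these floors and the intervals below cover counting error only. Each value sums both arms of a hairpin and holds only reads placed at a single genomic position.

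By reads placed at a single genomic position, Mir99a was the most abundant miRNA gene, at 134777 ± 6076 CPM or 13.5% ± 0.608 of the counts. Reads that match several positions are in none of the ranks given here. Mir335, which lies in an intron of the imprinted gene Mest, followed at 59015 ± 5121 CPM, and Mir100, a family member of Mir99a, reached 55011 ± 3914 CPM. Mir17, a member of the growth-promoting miR-17-92 cluster, had 50795 ± 3598 CPM and Mir130a had 32481 ± 537 CPM. The ratio of Mir99a to Mir335 was 2.36 in replicate 1 and 2.22 in replicate 2, so the lead of Mir99a was larger than the spread between the replicates. The next genes were Mir99b (29091 ± 2678 CPM), Mir10a (26113 ± 330 CPM), Mir30e (25170 ± 447 CPM), Mir126a (24715 ± 1800 CPM) and Mir26b (21662 ± 449 CPM). Together these 10 genes held 45.9% ± 1.25 of the counts, and the top 25 held 66.6% ± 1.56. Ranks 11 to 25 ran from Mirlet7g (21135 ± 1450 CPM) and Mir322 (20633 ± 2199 CPM) down to Mir342 (9955 ± 1299 CPM). Among these, Mir140, known from developing cartilage, had 11157 ± 2265 CPM, Mir23b had 10565 ± 1444 CPM and Mir181c had 10413 ± 533 CPM. Mir23b shares sequence with Mir23a. Of the 1973 miRNA genes in the tables, 371 had at least 10 counts in both libraries and are called detected, while 1238 had no count in either. With a minimum of 1 count in both libraries the number was 616. In all, 105 genes reached 1000 CPM.

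**Figure D1:**
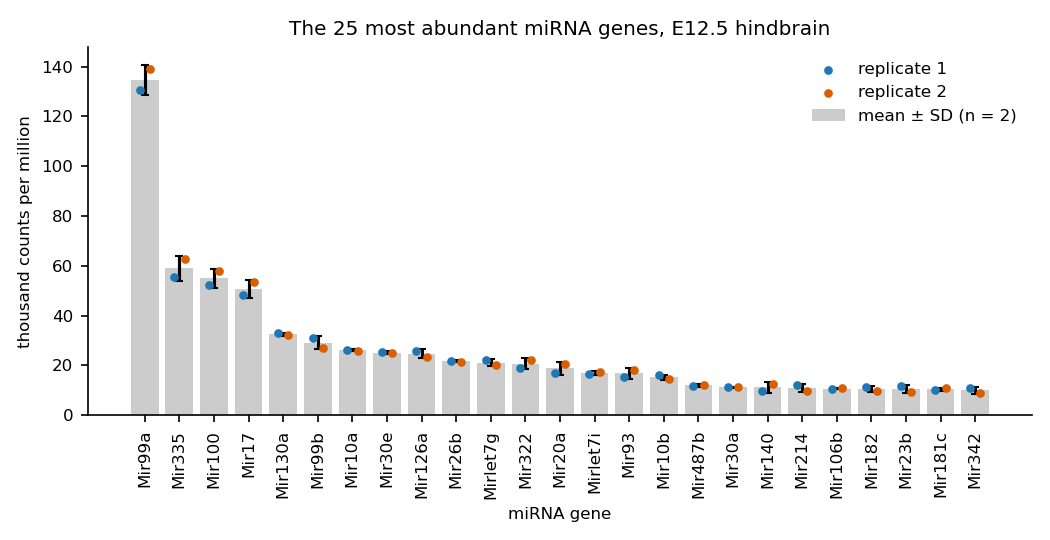
Abundance of the 25 most abundant miRNA genes in E12.5 hindbrain by reads placed at a single position, in units of 1000 CPM. Bars show the mean, error bars the SD of n = 2 libraries, and dots the libraries; Mir99a stands at 134777 ± 6076 CPM, above Mir335 at 59015 ± 5121 CPM.

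The most abundant genes lay in known miRNA loci of the GRCm38 assembly. Mir99a (ENSMUSG00000065530.1) is on chromosome 16 from 77598936 to 77599000, in an intron of the noncoding host gene Mir99ahg. Mir335 (ENSMUSG00000065501.1) is on chromosome 6 from 30741299 to 30741396. Mir100 (ENSMUSG00000093011.1) is on chromosome 9 from 41531425 to 41531504, in an intron of a noncoding transcript. Mir17 (ENSMUSG00000065508.1) is on chromosome 14 from 115043671 to 115043754, in an exon of Mir17hg. Mir126a (ENSMUSG00000065540.1) is on chromosome 2 from 26591357 to 26591429, inside the transcribed region of Egfl7, an endothelial gene.

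Among the miRNA lists, the miR-125 and miR-99/100 families, which are abundant in the developing nervous system, held the largest share, at 22.7% ± 0.619 of the counts. Mir99a, Mir100 and Mir99b made up most of it, while Mir125a (chosen after its value was seen) had 5081 ± 1046 CPM, and the miR-125b copies share sequence and lose reads that match both. The miR-17-92 cluster and its paralogous clusters, known for promoting proliferation, held 12.4% ± 0.523, and all 16 members were detected. Its leading genes were Mir17, Mir20a (18801 ± 2775 CPM) and Mir93 (16809 ± 2112 CPM), with Mir106b at 10709 ± 120 CPM. The miR-181, miR-30, miR-26 and miR-29 families together held 9.28% ± 0.0550, with 17 of 19 members detected. Mir30e and Mir26b led this list, followed by Mir30a (11339 ± 201 CPM). The let-7 family, which promotes differentiation and exit from the cell cycle, held 4.38% ± 0.163, with 11 of 12 members detected. Mirlet7g and Mirlet7i (17028 ± 719 CPM) gave most of these counts, and Mirlet7d had 2181 ± 610 CPM. The 5 let-7a, let-7c and let-7f genes counted here share sequence and averaged 179 CPM, against 10298 CPM for 4 let-7 genes that do not, so reads that match several copies are missing from the let-7 share. Reads on the strand opposite to Gm25927, where the annotation places Mirlet7e, are outside it as well and came to 5177 CPM in replicate 1 and 4170 CPM in replicate 2, more than Mirlet7d had in each library. By counts on the gene's own strand, the shares of let-7 and of the Hox cluster list overlapped over the libraries, whereas the other lists in this paragraph were apart from each other in both libraries. Without Mir99a in the counts, the miR-125 and miR-99/100 share was 10.7% and no longer the largest. The miR-17-92 share was then 14.3% and that of the miR-181, miR-30, miR-26 and miR-29 families 10.7%.

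The hindbrain carried high counts of the miRNAs encoded inside the Hox clusters, whose genes set anterior-posterior identity in the hindbrain and spinal cord. This list held 4.35% ± 0.156 of the counts, and 4 of its 6 members were detected. Mir10a, beside Hoxb4, had 26113 ± 330 CPM and Mir10b, in an intron of Hoxd4, had 15264 ± 1037 CPM. Mir10a exceeded Mir10b by 1.65-fold in replicate 1 and 1.78-fold in replicate 2. Mir615, in an intron of Hoxc5, had 2099 ± 196 CPM. Mir10a lies on chromosome 11 from 96317165 to 96317274, Mir10b on chromosome 2 from 74726070 to 74726137, and Mir615 on chromosome 15 from 103014910 to 103015001. The remaining members belong to the miR-196 family, which lies near more posterior Hox genes, and Mir196b (chosen after its value was seen) had 30.6 ± 7.97 CPM.

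The listed miRNAs of the imprinted Dlk1-Dio3 region, which are expressed from the maternal chromosome and are abundant in embryonic and neural tissue, held 6.43% ± 0.292 of the counts on the gene's own strand. Of 47 members, 41 were detected, and 14 reached 1000 CPM. By counts on the gene's own strand, Mir487b was the highest at 11971 ± 434 CPM, followed by Mir127 (6856 ± 577 CPM) and Mir369 (6450 ± 459 CPM). Reads on the strand opposite to Gm24321, where the annotation places Mir409 of this region, are outside this order and share. They came to 7670 CPM in replicate 1 and 7007 CPM in replicate 2. Reads opposite to Gm25252, Gm25750 and Mir299b, at Mir376a, Mir380 and Mir299a of the region, are outside as well. In replicates 1 and 2 these came to 2227 and 2632, 1128 and 1484, and 1161 and 1093 CPM. The 46 members on chromosome 12 span positions 109563692 to 109747960. Mir341, Mir1188 and Mir666 are detected genes within this span that are not on the list. Mir487b, at 109727333 to 109727414, shares an identical run of 20 bases with Mir376b, so its count is uncertain. Mir127 lies at 109592846 to 109592915, and Mir369 at 109743418 to 109743496 in an exon of the noncoding gene Mirg.

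**Figure D2:**
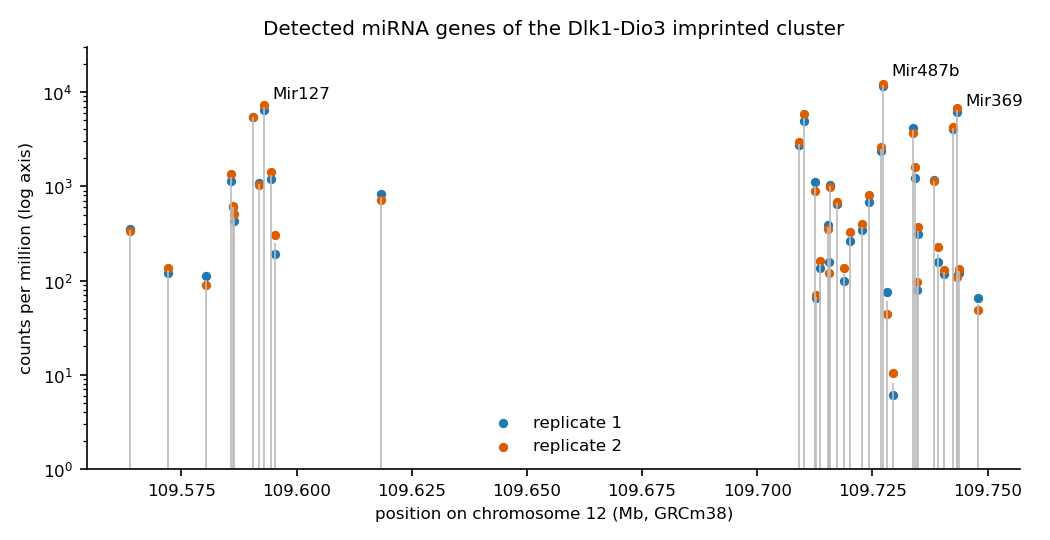
CPM (log axis) of the 41 detected members of the Dlk1-Dio3 imprinted region list against position on chromosome 12 (GRCm38). Dots are the libraries and grey lines reach the mean of n = 2; Mir487b is the highest gene by counts on its own strand, at 11971 ± 434 CPM.

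Neuronal miRNAs outside the miR-9 and miR-124 genes held 0.774% ± 0.0331 of the counts, and all 18 members were detected. Mir137, a regulator of neuronal differentiation, led with 3303 ± 56.2 CPM, followed by Mir153 (1465 ± 211 CPM) and Mir138-1 (456 ± 87.9 CPM). Mir138-1 shares sequence with Mir138-2. The miR-9 genes, which act in neural progenitors, held 0.0384% ± 0.00214, nearly all of it from Mir9-3 (382 ± 21.9 CPM). Reads on the strand opposite to Gm25641, where the annotation places Mir9-1, are outside this share. They came to 33.6 CPM in replicate 1 and 42.3 CPM in replicate 2. The miR-124 genes, which mark neurons, held 0.00130% ± 5.06e-05, with Mir124a-2 at 9.93 ± 0.789 CPM. All 5 of the miR-9 and miR-124 genes with counts share an identical run of 20 bases with another copy, so reads that match several copies are not in these values. Without genes that share sequence, both lists had a share of 0. These values are therefore no measure of total miR-9 or miR-124 in the tissue.

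Endothelial and sensory organ miRNAs were the most abundant of the lists for other cell types. Mir126a, the miRNA of endothelial cells, held 2.47% ± 0.180 of the counts. The miR-183 cluster of sensory organs, made of Mir182 (10658 ± 1248 CPM), Mir183 (6419 ± 1649 CPM) and Mir96 (2498 ± 713 CPM), held 1.96% ± 0.361. The mesenchyme list held 1.19% ± 0.147, mainly from Mir214 (10930 ± 1718 CPM), with Mir199b at 821 ± 211 CPM and Mir199a-2 at 123 ± 29.0 CPM. Both of the latter genes share sequence with other miR-199 copies. The smooth muscle and pericyte list held 0.959% ± 0.176, with Mir143 at 9443 ± 1725 CPM and its neighbour Mir145a at 148 ± 33.1 CPM. Mir143 exceeded Mir145a by 66.1-fold in replicate 1 and 62.2-fold in replicate 2. The epithelium list held 0.806% ± 0.226, led by Mir203 (2192 ± 52.8 CPM), Mir429 (2156 ± 1123 CPM) and Mir205 (1365 ± 133 CPM). The miRNAs of multiciliated cells, which line brain ventricles later in life, held 0.777% ± 0.107, with Mir449a at 6256 ± 952 CPM, Mir34c at 1437 ± 97.7 CPM and Mir34b at 50.2 ± 7.52 CPM.

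Glial, choroid plexus, blood and embryonic stem cell miRNAs each held under 1% of the counts. The oligodendrocyte list held 0.460% ± 0.125, from Mir219a-2 (4100 ± 1206 CPM), Mir219a-1 (409 ± 24.7 CPM) and Mir338 (95.5 ± 19.4 CPM). Mir219a-1 and Mir219a-2 share sequence, and without genes that share sequence the oligodendrocyte share was 0.0104%. The pluripotency clusters, known from embryonic stem cells and early embryos, held 0.343% ± 0.0488, led by Mir302a (1277 ± 72.0 CPM), Mir302d (1100 ± 132 CPM) and Mir302b (852 ± 249 CPM). Without genes that share sequence, which removes Mir302a and Mir302b, this share was 0.141%. Mir204 and Mir211, of choroid plexus and pigment epithelium, held 0.160% ± 0.00242, with Mir204 at 1588 ± 22.3 CPM and Mir211 at 16.9 ± 1.90 CPM. Mir375, an endocrine miRNA, held 0.153% ± 0.0217.

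Blood cell miRNAs were low. By counts on the gene's own strand, the leukocyte and microglia list held 0.0520% ± 0.00779, led by Mir223 (259 ± 48.2 CPM), Mir155 (202 ± 9.45 CPM) and Mir146 (43.0 ± 14.9 CPM). Reads on the strand opposite to Mir142b, where the annotation places Mir142, are outside this order. They came to 364 CPM in replicate 1 and 344 CPM in replicate 2, more than Mir223 had in each library. With both strands counted together the share of this list was 0.0853%. The erythroid list held 0.0327% ± 0.00402, with Mir451a at 285 ± 44.2 CPM, Mir144 at 23.1 ± 0.0663 CPM and Mir486 at 18.5 ± 3.98 CPM. The liver and gut list held 0.0163% ± 0.000985, with Mir192 at 85.5 ± 5.49 CPM, Mir194-2 at 66.0 ± 3.37 CPM and Mir122 at 11.1 ± 1.71 CPM. Without genes that share sequence the liver and gut share was 0.0105%. The skeletal and heart muscle list held 0.0412% ± 0.0333, with 0.0177% in replicate 1 (exact Clopper-Pearson 95% interval 0.0162% to 0.0193%) and 0.0647% in replicate 2 (0.0623% to 0.0673%). Its members Mir1a-1, Mir133a-1 and Mir133a-2 share sequence with other hairpins and had at most 1 count in a library. Reads that match several copies are not in this share. Of the 253 pairs among the 23 lists, 242 had ranges over the libraries that did not overlap. Lists were not tested against each other, since an exact two-sided sign-flip test over 2 libraries gives a p of at least 0.5.

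**Figure D3:**
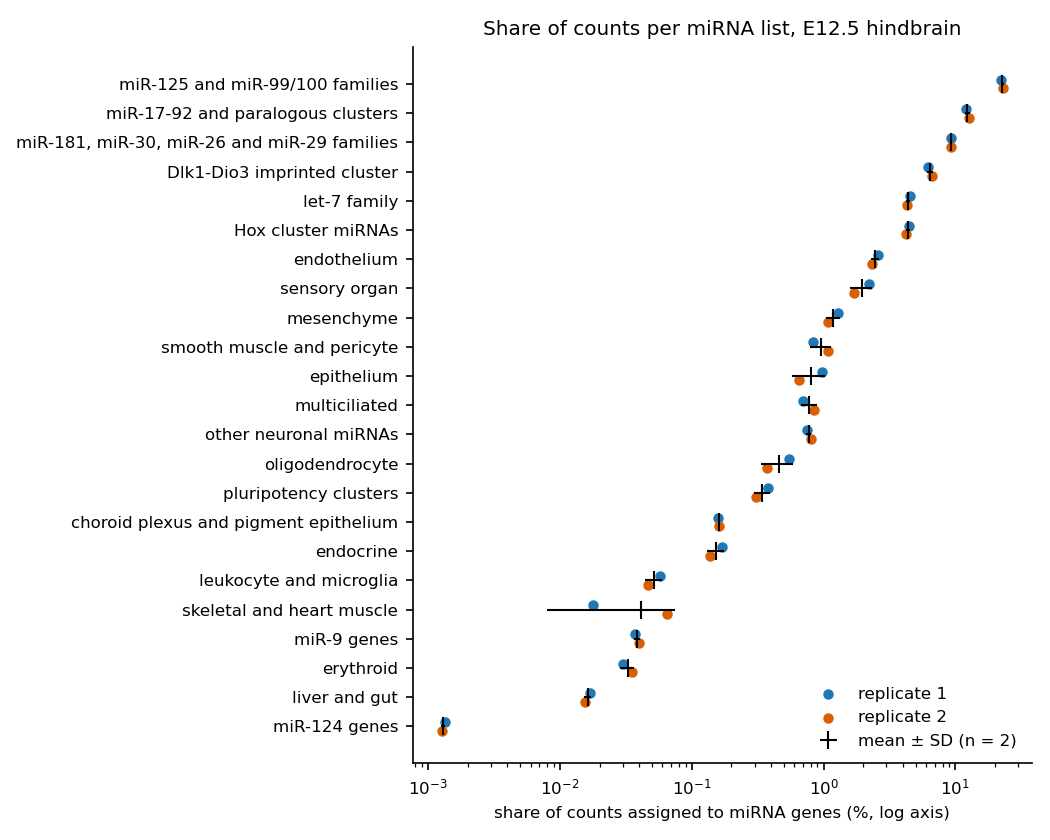
Share of assigned counts (percent, log axis) of each of the 23 miRNA lists in E12.5 hindbrain. Dots are the libraries and bars the mean ± SD (n = 2); the shares run from 22.7% for the miR-125 and miR-99/100 families to 0.00130% for the miR-124 genes, and the muscle list has the largest ratio between the libraries.

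The replicates had closely matching profiles for abundant miRNAs such as Mir130a (32860 CPM in replicate 1 and 32101 in replicate 2), Mir10a (26347 and 25880), Mir30e (25487 and 24854) and Mir106b (10624 and 10794). These were picked as close examples, while Mir140 (9555 and 12758) and Mir214 (12145 and 9714) differed more. Of the 105 genes at 1000 CPM or more, 100 differed by less than 1.5-fold, with a median absolute log2 ratio of 0.17. Among called genes with a mean of at least 100 counts, the largest differences were in Mir206, a miRNA of skeletal muscle, which was higher in replicate 2, and in Mir200c and Mir429, miRNAs of epithelial cells, which were lower in replicate 2. Over the 393 genes with a mean of at least 10 counts, the Pearson correlation of log2(CPM + 1) across genes was 0.993 and Spearman's rho was 0.991. Genes are not independent replicates, so these correlations are descriptive. The median absolute log2 ratio was 0.24, and 332 genes (84.5%) lay within 1.5-fold. The coefficient of variation between the libraries beyond counting noise, from the common dispersion of edgeR, was 17.4%. The counts differed by more than the sampling noise of independent reads (chi-square 104 per degree of freedom), so the tables are not copies of the same reads, while the separation of the pools rests on the labels.

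**Figure D4:**
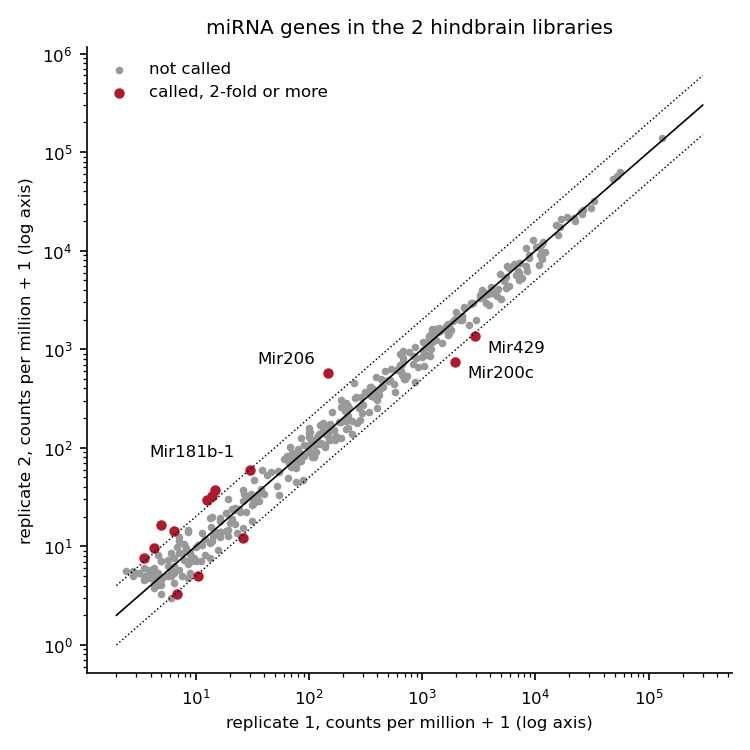
CPM + 1 of the 393 tested miRNA genes in replicate 1 (x axis) and replicate 2 (y axis), both log axes. The solid line marks equal values, the dotted lines a 2-fold difference, and red dots the 14 called genes, of which the 4 with a mean of at least 100 counts are named.

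The muscle miRNA Mir206 was higher, and the epithelial miRNAs Mir200c and Mir429 were lower, in replicate 2 than in replicate 1. Mir206 had 146 CPM (404 counts) in replicate 1 and 579 CPM (2285 counts) in replicate 2, a 3.96-fold difference. Mir200c was 2.62-fold lower in replicate 2 (1959 against 746 CPM) and Mir429 was 2.17-fold lower (2950 against 1362 CPM). Mir181b-1 was 2.03-fold higher in replicate 2 (28.9 against 59.0 CPM) and shares sequence with Mir181b-2. In the muscle list 4 of 6 tested members were called, all higher in replicate 2. Beside Mir206 these were Mir208b (13.0 against 31.7 CPM), Mir499 (3.98 against 15.5 CPM) and Mir133b (5.43 against 13.4 CPM). The members not called were Mir208a (5.06 against 4.05 CPM) and Mir1b (3.26 against 3.55 CPM), and these and Mir133b were named after their values were seen. In the epithelium list 2 of 7 tested members were called, both lower in replicate 2, while Mir203 (2230 against 2155 CPM) and Mir205 (1271 against 1459 CPM) were not called. The remaining members, named after their values were seen, were Mir200b (866 against 468 CPM) and Mir141 (238 against 136 CPM), which were lower in replicate 2 by less than 2-fold, and Mir200a (146 against 143 CPM). In the sensory organ list all 3 tested members were lower in replicate 2 and none reached 2-fold, and Mir183 (7585 against 5253 CPM) and Mir96 (3003 against 1994 CPM) were the farthest apart. The multiciliated, pluripotency and miR-181, miR-30, miR-26 and miR-29 lists had 1 called member each, and no other list had any. Adjusted over the list alone, the counts of called members were the same in each list.

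In all, 14 of 393 genes were called as differing between the libraries at an adjusted p under 0.05 and at least 2-fold, 9 higher and 5 lower in replicate 2. The test was a two-sided exact binomial test per gene with Benjamini-Hochberg adjustment. Without the minimum of 2-fold, 203 genes were called, and with a mean of at least 100 counts the 2-fold calls were Mir206, Mir200c, Mir429 and Mir181b-1. The largest adjusted exact p among these 4 was 3.82e-08, for Mir181b-1. This test compares the reads of these 2 libraries only, and does not measure variation between further pools of embryos.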

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

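All tests in this part were chosen after the results were seen. Reads on the strand opposite to the annotated gene lie outside the main measurement, and they numbered 67385 in replicate 1 and 94907 in replicate 2, where a count of 0 would allow 3. They fell in few genes. By replicate 2, the highest were Gm24321 (21202 and 27654 opposite-strand counts), Gm25301 (9067 and 16861), Gm25927 (14312 and 16458) and Gm25252 (6155 and 10386). Next came Gm24083 (7643 and 9701), which was above Gm25252 in replicate 1. Each of these had no count on its own strand. Their overlapping M21 genes on the other strand are, in the same order, Mir409, Mir378a, Mirlet7e, Mir376a and Mir191. These partners are not counted on their own strand here.

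A loss of strand information in every gene is argued against, because the median opposite-strand share was 0% over the 161 genes with at least 1000 counts in each library. Of these genes, 152 had under 1% and 9 over 90% of their counts on the opposite strand. Genes that overlap an M21 miRNA gene on the other strand held at least 99.8% of the opposite-strand counts in both libraries, and 12 of the 13 genes with at least 10 such counts in both were of this kind. The remaining gene was Mir203, with 32 and 60. A candidate explanation is that these reads come from the partner genes, which would place Mir409 and Mirlet7e among the abundant hairpins of the tissue. No biological explanation was tested.

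Reads that match several positions were also outside the main measurement, at 32.7% of all reads in replicate 1 and 33.4% in replicate 2. Of the aligned reads they were 39.3% on average, and the miRNAs they come from are not recorded in the tables used here. This bears on the low counts of the miR-9 and miR-124 genes. Reads of identical copies are left out by the counting, and a candidate explanation is that this loss accounts for the low counts. In families with both kinds of genes, those that share sequence had the lower mean CPM in 10 of 14 families, with an exact two-sided sign test p of 0.18. The median log2 ratio of sharing over other genes was -2.03. Of the families that went the other way, miR-28 and miR-669 had other genes at 0.977 and 0 CPM. The miR-302 and miR-7 families had them at 618 and 247 CPM. A low abundance of miR-9 and miR-124 in the tissue cannot be told apart from the loss, since the reads that match several positions are not split by miRNA.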

How the results depend on the processing

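All alternatives in this part were planned. The count of called genes, the correlation and the spread use both libraries, so leaving a library out gives no value for them. The correlation stayed at 0.993 to 0.995 and the spread at 16.6% to 18.4% under all alternatives run, and the calls of Mir206, Mir200c, Mir429 and Mir181b-1 held wherever these genes were tested. Of 686 alternative values, 567 stayed within a limit and 119 moved beyond it. The limit was the SD between the replicates for shares and CPM, and a fixed change for counts, the correlation and the spread. Log2 ratios of Mir206, Mir200c, Mir429 and Mir181b-1 were instead judged by whether the gene was still called. Only these ratios could be counted as reversed, and 0 were. For list shares and CPM, leaving out a library could not count as a move. Either of 2 libraries always lies within the SD of their mean. Such values among the 567 are therefore no sign of stability. The same holds for shares and CPM under TMM or DESeq2 size factors, for the reason given below. Depth limits what a count of 0 excludes, at 1.09 CPM in replicate 1 and 0.760 CPM in replicate 2. Of genes under 100 CPM, 122 of 167 lay within 1.5-fold, against 100 of 105 at 1000 CPM or more, and the cause was not tested.

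Each library alone gave 385 to 403 detected genes and a top 10 share of 45.0% to 46.8%. A minimum of 1 count gave 616 detected genes. The top 10 share was 49.9% without genes that share sequence and 39.9% without Mir99a. The called genes numbered 4 with a mean of at least 100 counts, since fewer genes are tested, and 203 with no minimum fold. With no filter on low counts 18 genes were called, 12 of them among the main 14. DESeq2 size factors kept 13 of the 14 calls and TMM all 14.

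TMM and DESeq2 size factors moved no list share by more than its SD. These factors act on the 2 libraries in opposite directions by nearly the same proportion, at 1.012 and 0.988 for DESeq2. The mean of the libraries therefore hardly moves, which is no sign of stability. With both strands together, the shares were 0.0413% for miR-9, 0.00144% for miR-124, 9.06% for miR-181, miR-30, miR-26 and miR-29, 0.157% for choroid plexus and 0.0853% for leukocytes. Without genes that share sequence, which removes members and lowers the total, they were 4.67% for let-7, 0% for miR-9 and for miR-124, 0.631% for other neuronal miRNAs, 24.3% for miR-125 and miR-99/100, 4.73% for Hox, 5.06% for Dlk1-Dio3, 9.21% for miR-181, miR-30, miR-26 and miR-29, 0.141% for pluripotency, 0.174% for choroid plexus, 0.0104% for oligodendrocytes, 2.69% for endothelium and 0.0105% for liver and gut.

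Without Mir99a the total falls and shares of other lists rise by a factor of 1.15 to 1.16. The shares past their SD were 5.07% for let-7, 0.0444% for miR-9, 0.00151% for miR-124, 0.895% for other neuronal miRNAs, 10.7% for miR-125 and miR-99/100, 14.3% for miR-17-92, 5.03% for Hox, 7.44% for Dlk1-Dio3, 10.7% for miR-181, miR-30, miR-26 and miR-29, 0.397% for pluripotency, 0.186% for choroid plexus, 0.0378% for erythroid, 0.0600% for leukocytes, 2.86% for endothelium, 1.37% for mesenchyme, 0.899% for multiciliated, 0.0188% for liver and gut and 0.177% for endocrine miRNAs. The muscle share was 0.0177% without replicate 2 and 0.0647% without replicate 1.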

Other observations

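The gene groups in this part and all tests in it were chosen after the results were seen. Some miRNAs of imprinted loci outside the Dlk1-Dio3 region were looked up beside Mir335 of the Mest locus, with no test of imprinted loci as a group. Mir296 (6221 ± 763 CPM, SD, n = 2) and Mir298 (4398 ± 389 CPM), neighbours in the imprinted Gnas region on chromosome 2, were both well above the 1000 CPM that 105 genes reached. Mir675, cut from the imprinted noncoding RNA H19, had 47.9 ± 15.0 CPM, and Mir184 on chromosome 9, reported as imprinted, had 2.93 ± 1.59 CPM. On the X chromosome, a cluster of 7 detected genes from 53047997 to 53054349 held 2.54% ± 0.237 of the counts. Mir322 made up most of it, while Mir351 had 3688 ± 0.975 CPM, Mir503 had 536 ± 89.2 CPM and Mir542 had 380 ± 42.4 CPM. Mir21a, a miRNA found in many cell types, had 6226 ± 572 CPM, and Mir210, which responds to low oxygen, had 604 ± 14.6 CPM.

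Neighbouring hairpins often differed in counts, and some of the low genes share sequence with other hairpins. With detected genes on the same strand joined when at most 10000 bases apart, 44 clusters held 156 genes and 60.8% ± 1.02 of the counts. The highest member exceeded the lowest by at least 10-fold in 27 clusters and by at least 100-fold in 11, with a median of 19.2-fold. In 8 of these 11 the lowest gene shares sequence with another hairpin. Without genes that share sequence, an alternative chosen after seeing the data, 26 clusters remained, of which 15 reached 10-fold and 5 reached 100-fold, with a median of 13.2-fold. In the miR-17-92 cluster on chromosome 14 the range was 2268-fold, from Mir17 (50795 ± 3598 CPM) to Mir19b-1 (22.4 ± 1.58 CPM), which shares sequence with Mir19b-2. For Mir19a, at 104 ± 28.3 CPM, no other hairpin has an identical run of 20 bases. A loss of its reads to other positions is not excluded, since the mismatch and length settings of the alignment are not given. Unlike in this cluster, Mir181c and Mir181d differed by 1.21-fold and Mir296 and Mir298 by 1.41-fold.

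Many lists had medians away from 0 between the replicates, both of other cell types and of neural or imprinted miRNAs. The median log2 ratio of replicate 2 over replicate 1 was 1.27 over 6 tested muscle miRNAs, 0.51 over 4 of mesenchyme, 0.31 over 5 of multiciliated cells, 0.21 over 18 other neuronal miRNAs and 0.13 over 41 of the Dlk1-Dio3 region. These 5 lists lay above percentile 95 of 10000 random lists matched on mean CPM. The mesenchyme total went the other way, at 1.29% of the counts in replicate 1 and 1.08% in replicate 2, since Mir214 holds 91.9% of it and had a log2 ratio of -0.32, while the 3 higher members are miR-199 genes that share sequence. It was -0.81 over 7 epithelial miRNAs, -0.53 over 3 of sensory organs, -0.52 over 4 of leukocytes, -0.45 over 8 of the pluripotency clusters and -0.42 over 3 of oligodendrocytes. These 5 lists lay below percentile 5. The remaining 7 of the 17 lists with at least 3 tested members lay between. Members of a list are often neighbours from the same transcript, so the percentiles are descriptive.

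Explanations were weighed for the muscle list and for the epithelial and sensory lists. GC content of the hairpins is argued against, since other genes of similar GC content did not move with the lists. The median log2 ratio was -0.0280 (bootstrap 95% interval -0.0780 to 0.0518) over 212 other tested genes matched on GC content to the muscle miRNAs, whose median was 1.27. It was 0.0324 (-0.0778 to 0.0853) over 165 matched to the epithelial and sensory miRNAs, whose median was -0.56. The muscle list had 489 counts in replicate 1 and 2555 in replicate 2, most of them from Mir206, and 85 and 270 without it. As a hypothesis, the dissections may have held different amounts of muscle, epithelial and sensory tissue. The medians lay at percentiles 99.99 and 0 of random lists matched on mean CPM, but the lists were picked for this pattern, so these percentiles do not test it. In muscle, 4 members had log2 ratios of 1.27 to 1.98, while Mir1b had 0.10 and Mir208a -0.33. Apart from Mir206, these ratios rest on few counts in replicates 1 and 2. Examples are 9 and 14 for Mir1b, 14 and 16 for Mir208a and 11 and 61 for Mir499. In epithelium, Mir200c (-1.39), Mir429 (-1.12), Mir200b (-0.89) and Mir141 (-0.81) were lower, while Mir200a (-0.03) and Mir203 (-0.05) were near 0 and Mir205 (0.20) was higher. All 3 sensory members were lower, at -0.24 for Mir182, -0.53 for Mir183 and -0.59 for Mir96, and they are neighbours on chromosome 6. The hypothesis and differences in library preparation or between the pools stay open.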
